A study of Mus musculus with 9 samples.

How the data were processed

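Gene expression was measured by RNA sequencing of mouse colon. Per the labels, C57BL/6 mice entered the study at 6 weeks of age in 3 groups of 15 (45 mice), and colon was taken at postnatal day 98. The 9 libraries analysed are 3 from control mice (replicates 1, 2 and 3), 3 from mice on a high-fat diet (HFD; replicates 1, 2 and 4) and 3 from mice on the high-fat diet that also received the gut bacterium Papillibacter cinnamivorans by gavage, which is dosing by a tube into the stomach (replicates 1, 3 and 4). The group of each library was taken from its treatment label and the replicate number from its title. The labels do not say which stretch of the colon was taken, and no sequencing batch or date is given.

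The authors deposited 1 table of FPKM values (fragments scaled by transcript length and by the mapped fragments of the library) with 54491 rows and 9 columns, of which 22310 rows were 0 in every library and 791 were unnamed gene models. Per the submitters' processing notes, reads were aligned with HISAT2 2.0.5 and the genome build was GRCm39. The counting tool and the annotation are not given in the sources used here. The reference at hand was GENCODE M21, which is on another build, so it served for gene symbols and exonic lengths and no coordinates are printed. A symbol was found for 52093 of the 54491 identifiers. Multi-copy transcripts appeared to be counted in part: Gapdh, which has many processed pseudogenes, ranged from 1.67 to 10.6 FPKM. Values of genes with near-identical copies are therefore uncertain.

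FPKM values are not counts, and the count test first planned for these comparisons was replaced by the test planned for normalised values. Differences were tested with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with a trend of variance on mean level, all 9 libraries in 1 fit and no covariate. The 17907 genes with at least 0.5 FPKM in at least 3 libraries were tested. P-values were adjusted by the Benjamini-Hochberg method within each of 3 comparisons, and a gene was called at an adjusted p below 0.05. Every log2 difference given is on the log2(FPKM + 1) scale, which understates the change of genes with low values. The labels do not say that each library came from a separate mouse. P-values therefore measure the spread between the 3 libraries of a group, pooled over all 3 groups, also in a comparison of 2 of them. The fit was applied to simulated data with the means and spread of these libraries and noise independent between genes. In them 200 genes drawn from those with higher levels in control were changed. For HFD against control the fit recovered 64% of changes of 1 log2 unit and 93% of changes of 2 log2 units. There were 11 false calls among 168 calls in 16967 tested genes. For HFD with the bacterium against HFD it recovered 50% and 91%, with 6 false calls among 147 calls in 16983 genes. For HFD with the bacterium against control it recovered 62% and 92%, with 8 false calls among 162 calls in 16951 genes. A deviation of 1 library shared by many genes was not simulated.

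Gene lists for pathways and cell types, 39 in all, were written before the data were examined, as were the main test, the rule for named genes and 19 alternative settings. The 36 lists with at least 5 tested genes were tested with camera at a preset inter-gene correlation of 0.01. The neutrophil, skeletal muscle and erythrocyte lists had 4 tested genes each and were not tested. Beside camera, each list was tested with an estimated correlation and with fry, which asks whether the genes of a list move on balance in the same direction without comparing them with other genes. Named genes were, per comparison, the 5 with the largest log2 difference in each direction among called genes whose groups did not overlap and whose mean over the 6 libraries was at least 1 FPKM, leaving out unnamed gene models, pseudogenes and variable segments of immunoglobulin and T cell receptor genes; the 3 members with the smallest p in the direction of each of the first 6 lists that passed; at most 1 called member of each other list; and 20 genes fixed in advance for gut barrier, inflammation, lipid metabolism and gut hormones. A list of ribosomal protein genes served the check of gene length. Hox genes, pan-epithelial genes, mitochondrially encoded genes and genes of sodium and potassium handling in the distal colon were grouped after the data had been seen.

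Total read numbers are unknown, since FPKM values carry no totals. Low values stood in ratios of whole numbers up to 20, within 0.0005 on the natural log scale, for 99.3% to 100% of the genes checked in each library against control replicate 1, which gave the relative depth. Relative to control replicate 1 it ranged from 0.822 in replicate 1 of HFD with the bacterium to 1.103 in HFD replicate 1. No gene had an identical value above 0 in any pair of libraries, and correlations within groups lay between 0.928 and 0.978. The alternatives were quantile normalization, limma without a trend, no filter, a filter of 1 FPKM, pseudocounts of 0.1 and 0.5, a fit of only the groups compared, the replicate number as a block, each library left out in turn, and 3 chosen after seeing the data: TPM scaling, removal of mitochondrial and immunoglobulin genes with median-ratio scaling, and an adjustment for gene length. Alternatives that need counts were not run.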

Results

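RNA of 9 colon libraries was compared between a control group, a group on a high-fat diet (HFD) and a group on the same diet that was gavaged with Papillibacter cinnamivorans, with 3 libraries in each. Values are FPKM as deposited, given as mean ± SD (n = 3 libraries). Relative sequencing depth differed by at most 1.342-fold between libraries, and total depth is unknown. The first principal component held 49.9% of the variance and set the 3 HFD libraries (scores 59.6 to 62.7) apart from the other 6 (-39.6 to -12.6). The second held 15.3% and set control replicate 1 (62.9) apart from the other 8 libraries (-20.9 to 6.4).

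The comparison of HFD with control asks how expression in the colon differed with the diet. A different tissue position of the HFD pieces, weighed under Other observations, could also enter it. In HFD colon, 1903 genes were higher and 1632 lower than in control (limma-trend, adjusted p below 0.05). Sval1 reached 813 ± 191 FPKM against 7.90 ± 6.99 in control (log2 difference 6.76, SE 0.50, limma adjusted p = 8.7e-05). Tgm3, a transglutaminase of cornifying epithelia, was at 365 ± 66.5 against 5.95 ± 9.52 FPKM, and S100g, a calcium-binding protein of the intestine, at 494 ± 118 against 20.4 ± 20.1 FPKM. The homeobox genes Hoxd13 and Hoxb13 were among the 5 named genes with the largest increase. Hoxd13 measured 86.0, 94.3 and 72.6 FPKM in the HFD libraries and 0.45, 0 and 0.0266 FPKM in control, and Hoxb13 measured 127 ± 8.03 against 2.63 ± 4.42 FPKM, with 7.73 FPKM in control replicate 1. Among the genes that were lower, Tmigd1 fell from 309 ± 165 to 1.71 ± 0.689 FPKM, Alpi, the intestinal alkaline phosphatase, from 82.9 ± 41.2 to 0.171 ± 0.109 FPKM, Cyp2c65 from 233 ± 180 to 0.929 ± 0.122 FPKM and Sptssb from 103 ± 73.3 to 0.0818 ± 0.0661 FPKM. Reg3b, an antimicrobial lectin, measured 24.7, 977 and 1430 FPKM in control and 1.96, 0 and 0 FPKM in HFD.

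Immune lists were higher in HFD colon. Of 23 B and plasma cell genes, 20 rose and 1 fell (20 and 1 adjusted over the list alone), with a median log2 difference of 2.58. The B cell genes Fcrla, Cd22 and Ms4a1 were at 8.18 ± 0.968, 8.21 ± 1.70 and 8.12 ± 0.510 FPKM against 0.505 ± 0.0958, 0.532 ± 0.216 and 0.429 ± 0.328 FPKM. Of 25 macrophage and dendritic cell genes 18 rose and none fell (20 adjusted over the list alone), among them Lyz2, a lysozyme of myeloid cells, at 341 ± 8.21 against 107 ± 14.0 FPKM. Of 14 genes of MHC class II antigen presentation 10 rose (13 adjusted over the list alone), with H2-Ob at 8.71 ± 1.07 against 0.628 ± 0.440 FPKM. Of 25 T and NK cell genes 15 rose (16 adjusted over the list alone), with Trac, the T cell receptor alpha constant region, at 18.6 ± 2.29 against 7.15 ± 2.14 FPKM. Of 21 inflammatory cytokine and NF-kB target genes 11 rose and 0 fell (12 and 2 adjusted over the list alone), with Cd14, a receptor for bacterial lipopolysaccharide, at 59.6 ± 5.21 against 19.4 ± 2.68 FPKM and Vcam1 at 5.67 ± 0.206 against 1.55 ± 0.202 FPKM. These lists passed camera with adjusted p from 4e-16 to 3.5e-05. With an estimated correlation the adjusted p was 0.16 for the B and plasma cell and MHC class II lists, 0.27 for the inflammatory list and 0.32 for the macrophage and T cell lists. In the same libraries, immunoglobulin transcripts took 9.23% ± 1.77 of summed FPKM in HFD and 0.889% ± 0.444 in control.

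Several lists of lipid handling and absorption were lower in HFD colon, while of 26 cholesterol biosynthesis genes 0 were called (0 adjusted over the list alone; median -0.19, camera adjusted p = 0.077). Of 35 genes of fatty acid oxidation and PPAR targets, 8 fell and 1 rose (10 and 1 adjusted over the list alone). Fabp2, the intestinal fatty acid-binding protein, fell from 1702 ± 876 to 23.4 ± 6.24 FPKM, and Pdk4, a kinase that inhibits pyruvate dehydrogenase, fell by 2.43 on the log2 scale (SE 0.39). The member that rose was Plin2, a lipid droplet protein (named after its value was seen). Of 14 bile acid transport and sensing genes 7 fell (9 adjusted over the list alone), with Slc51b, a subunit of the basolateral bile acid exporter, at 16.8 ± 3.97 against 109 ± 30.4 FPKM. Of 24 fatty acid and triglyceride synthesis genes 10 fell and 3 rose (11 and 4 adjusted over the list alone), and of 22 small intestine enterocyte genes 8 fell (11 fell and 1 rose adjusted over the list alone). Of 25 enteric neuron and glia genes 9 fell (13 adjusted over the list alone), with Gfap, a glial filament protein, at 0.80 ± 0.0756 against 2.20 ± 0.584 FPKM. These lists passed camera with adjusted p from 2.1e-06 to 0.00048, and with an estimated correlation each had an adjusted p of 0.74. The mast cell, fibroblast, interferon-stimulated, cell cycle and pancreatic acinar lists also passed camera as higher, but with an estimated correlation their adjusted p was 0.74, 0.79, 0.79, 0.79 and 0.32. Cma1, a mast cell chymase, measured 9.39, 12.9 and 14.6 FPKM in HFD and 0, 0.424 and 0 FPKM in control, and Cela1, a pancreatic elastase, was at 91.8 ± 10.1 against 22.5 ± 2.33 FPKM. The adipocyte, xenobiotic, smooth muscle and oxidative phosphorylation lists passed camera as lower (adjusted p 0.74, 0.79, 0.80 and 0.79 with an estimated correlation), with Slc2a4, an insulin-responsive glucose transporter, at 4.77 ± 0.174 against 16.0 ± 4.41 FPKM and Ndufa2, a subunit of respiratory complex I, at 86.9 ± 12.2 against 186 ± 14.2 FPKM. Mitochondrial transcripts took 11.6% ± 1.91 of summed FPKM in HFD and 21.7% ± 4.50 in control. Without control replicate 1 the smooth muscle and mast cell lists no longer passed; the smooth muscle gene Des (named after its value was seen, not called) measured 1180, 242 and 160 FPKM in control replicates 1, 2 and 3 and between 138 and 176 FPKM in HFD. The pancreatic acinar list did not with TPM scaling or after removal of mitochondrial and immunoglobulin genes. In all, 19 of 36 lists passed camera and 0 passed with an estimated correlation, the lowest adjusted p being 0.16, while fry passed 8. These were the B and plasma cell, MHC class II, inflammatory, macrophage, T and NK cell, mast cell and pancreatic acinar lists (fry adjusted p from 0.00013 to 0.0039). The last was fatty acid and triglyceride synthesis (0.033). Fatty acid oxidation (0.08), bile acid (0.08), small intestine enterocyte (0.057) and enteric neuron (0.095) lists did not pass fry.

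**Figure D1:**
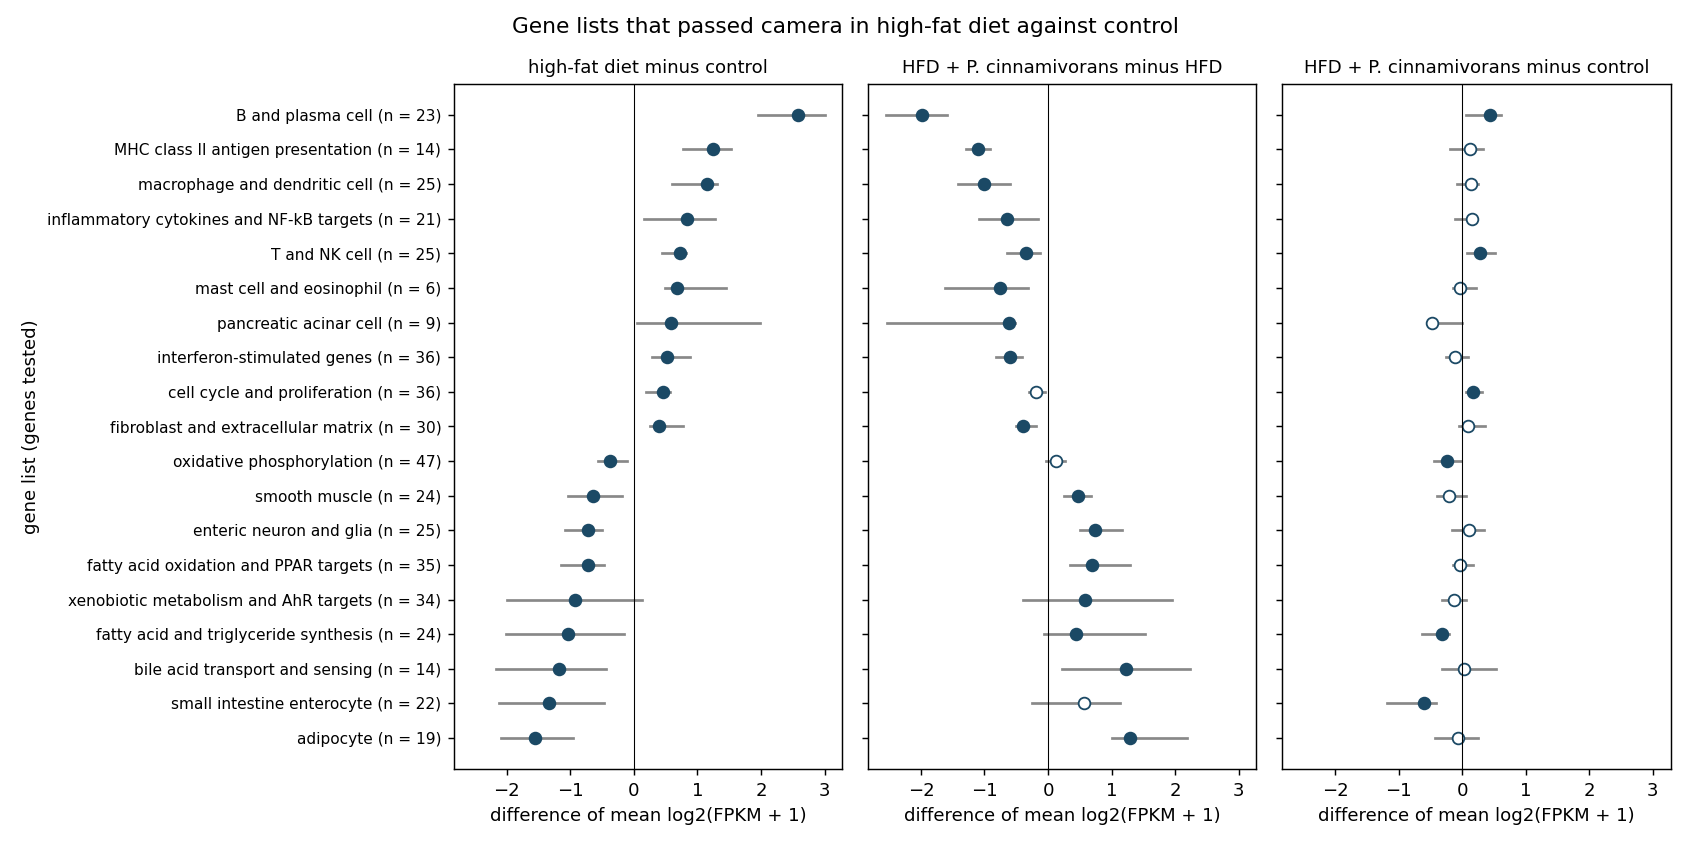
Median difference of mean log2(FPKM + 1) (horizontal axis) of the 19 gene lists that passed camera in HFD against control (vertical axis, number of tested genes in parentheses), in each of the 3 comparisons. Bars span the quartiles of the list's genes, and filled points passed camera in that comparison. The B and plasma cell list lies at 2.58 in HFD against control and at -1.99 in HFD with the bacterium against HFD.

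Members of several lists moved in both directions. Of 33 colonocyte genes, 6 rose and 10 fell (8 and 10 adjusted over the list alone; camera adjusted p = 0.44); Best2, a chloride and bicarbonate channel, was at 18.7 ± 0.878 against 1.22 ± 0.554 FPKM. Of 25 junction genes 3 rose and 5 fell (3 and 7 adjusted over the list alone), and Cldn8, a claudin, was at 67.2 ± 5.51 against 8.10 ± 2.69 FPKM. Of 28 antimicrobial genes 8 rose and 5 fell (9 and 7 adjusted over the list alone), and Sprr1a fell from 130 ± 39.6 to 5.22 ± 1.37 FPKM. Of 22 goblet cell genes 1 rose and 5 fell (1 and 5 adjusted over the list alone), including Muc2, the main secreted mucin of the colon, from 344 ± 73.1 to 105 ± 10.9 FPKM. Sst, which encodes somatostatin, fell from 118 ± 24.0 to 15.8 ± 1.01 FPKM. The Hox genes named above belong to a wider pattern grouped after the values were seen: of 9 tested posterior Hox genes (groups 10 to 13 and Evx2) 6 were higher and 0 lower in HFD than in control (7 and 1 adjusted over the list alone), and of 7 genes from Hoxb2 to Hoxb8, 0 were higher and 6 lower (0 and 7 adjusted over the list alone). Hoxd12, Hoxd13 and Evx2 passed the filter only through the HFD libraries, so they could only come out higher there. Of the 14 genes in the posterior list, Hoxc10, Hoxc11, Hoxc12, Hoxc13 and Evx1 did not pass the filter. Hoxc10 and Hoxc11 had means of 0 FPKM in HFD and low means of 0.277 and 0.196 FPKM in control. Hoxa11 was at 1.81 ± 0.163 FPKM in HFD against 5.93 ± 5.30 in control. Control replicate 1 lay apart from control replicates 2 and 3 in several of these genes, with Hoxa13 at 26.0, 2.06 and 0.385 FPKM in control replicates 1, 2 and 3 and between 31.3 and 36.0 FPKM in HFD. The number of called genes, 3535, was 1718, 1858 and 1612 without HFD replicate 1, 2 or 4 and 2234 without control replicate 2. With TPM scaling 78.2% of called genes were higher, against 53.8% as tested, and the median of all genes moved to 0.218.

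The comparison of HFD with P. cinnamivorans against HFD asks what differed in mice on the diet that were given the bacterium. The labels name gavage only for the group with the bacterium, so the bacterium and the gavage procedure cannot be told apart. A different tissue position of the HFD pieces, weighed under Other observations, could also enter this comparison. Here 813 genes were higher and 1361 lower with the bacterium. Cyp2c65 was at 300 ± 33.8 against 0.929 ± 0.122 FPKM in HFD (log2 difference 7.28, SE 0.75, limma adjusted p = 0.00054), Tmigd1 at 399 ± 119 against 1.71 ± 0.689 FPKM, Sptssb at 124 ± 27.0 against 0.0818 ± 0.0661 FPKM and Car1, a carbonic anhydrase, at 9200 ± 1303 against 88.4 ± 31 FPKM. Tgm3 fell from 365 ± 66.5 to 2.54 ± 2.35 FPKM, Sval1 from 813 ± 191 to 6.84 ± 3.73 FPKM and Ly6g from 292 ± 37.6 to 2.84 ± 1.98 FPKM. Hoxb13 fell from 127 ± 8.03 to 0.809 ± 1.16 FPKM, and Hoxd13 measured 0, 0.0483 and 0.137 FPKM with the bacterium. Of the 9 tested posterior Hox genes 5 were lower and 0 higher with the bacterium (6 and 0 adjusted over the list alone). The limit from the filter given above for Hoxd12, Hoxd13 and Evx2 holds here too. Of Hoxb2 to Hoxb8 6 were higher and 0 lower (7 and 0 adjusted over the list alone).

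Immune lists were lower with the bacterium. Of 23 B and plasma cell genes 18 fell and 1 rose (19 and 1 adjusted over the list alone), with Ms4a1 at 0.437 ± 0.158 against 8.12 ± 0.510 FPKM. Of 25 macrophage and dendritic cell genes 18 fell (19 adjusted over the list alone), with Itgax at 2.20 ± 0.255 against 6.34 ± 1.13 FPKM. Of 14 MHC class II genes 11 fell (14 adjusted over the list alone), and of 36 interferon-stimulated genes 6 fell (13 adjusted over the list alone), with Oas1a at 44.5 ± 5.51 against 81.5 ± 14.5 FPKM. Of 35 genes of fatty acid oxidation and PPAR targets 7 rose and 1 fell (8 and 1 adjusted over the list alone), with Pdk4 at 40.8 ± 20.6 against 3.30 ± 0.698 FPKM. Of 25 enteric neuron and glia genes 7 rose (12 adjusted over the list alone), with Gal, which encodes the neuropeptide galanin, at 43.8 ± 23.5 against 4.38 ± 0.785 FPKM. In the same libraries immunoglobulin transcripts took 1.99% ± 1.11 of summed FPKM with the bacterium against 9.23% ± 1.77 in HFD, and mitochondrial transcripts 28.2% ± 6.60 against 11.6% ± 1.91. These lists passed camera with adjusted p from 1.5e-15 to 6.8e-06. With an estimated correlation the adjusted p was 0.18 for the B and plasma cell and MHC class II lists, 0.37 for macrophages, 0.68 for fatty acid oxidation and for enteric neurons and 0.71 for interferon-stimulated genes. Of 21 inflammatory genes 8 fell and 1 rose (11 and 1 adjusted over the list alone; camera adjusted p = 2.2e-05, 0.21 with an estimated correlation). Of 13 tuft cell genes 5 rose (6 adjusted over the list alone; camera adjusted p = 0.0036, 0.67 with an estimated correlation), with Sh2d6 at 4.96 ± 1.04 against 1.42 ± 0.370 FPKM. Sh2d6 was not called without HFD replicate 1 or 4 or replicate 1 of the group with the bacterium. The adipocyte (median 1.29) and smooth muscle (median 0.47) lists also passed camera as higher, as did the bile acid, fatty acid and triglyceride synthesis and xenobiotic lists. The T and NK cell, mast cell, fibroblast and pancreatic acinar lists passed as lower. With an estimated correlation the adjusted p of these lists lay between 0.21 and 0.92. In all, 17 of 36 lists passed camera, 0 passed with an estimated correlation and 7 passed fry. The B and plasma cell, MHC class II, inflammatory, macrophage, mast cell, pancreatic acinar and tuft cell lists passed fry (adjusted p from 0.00027 to 0.037). The T and NK cell (0.055), enteric neuron (0.09), fatty acid oxidation (0.12) and interferon-stimulated (0.13) lists did not. The number of called genes, 2174, was 991, 1004 and 1202 without HFD replicate 1, 2 or 4, 1291 and 1419 without replicate 1 or 4 of the group with the bacterium, and 3603 without control replicate 1. With TPM scaling 25% of called genes were higher, against 37.4% as tested, and the median of all genes moved to -0.179.

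**Figure D2:**
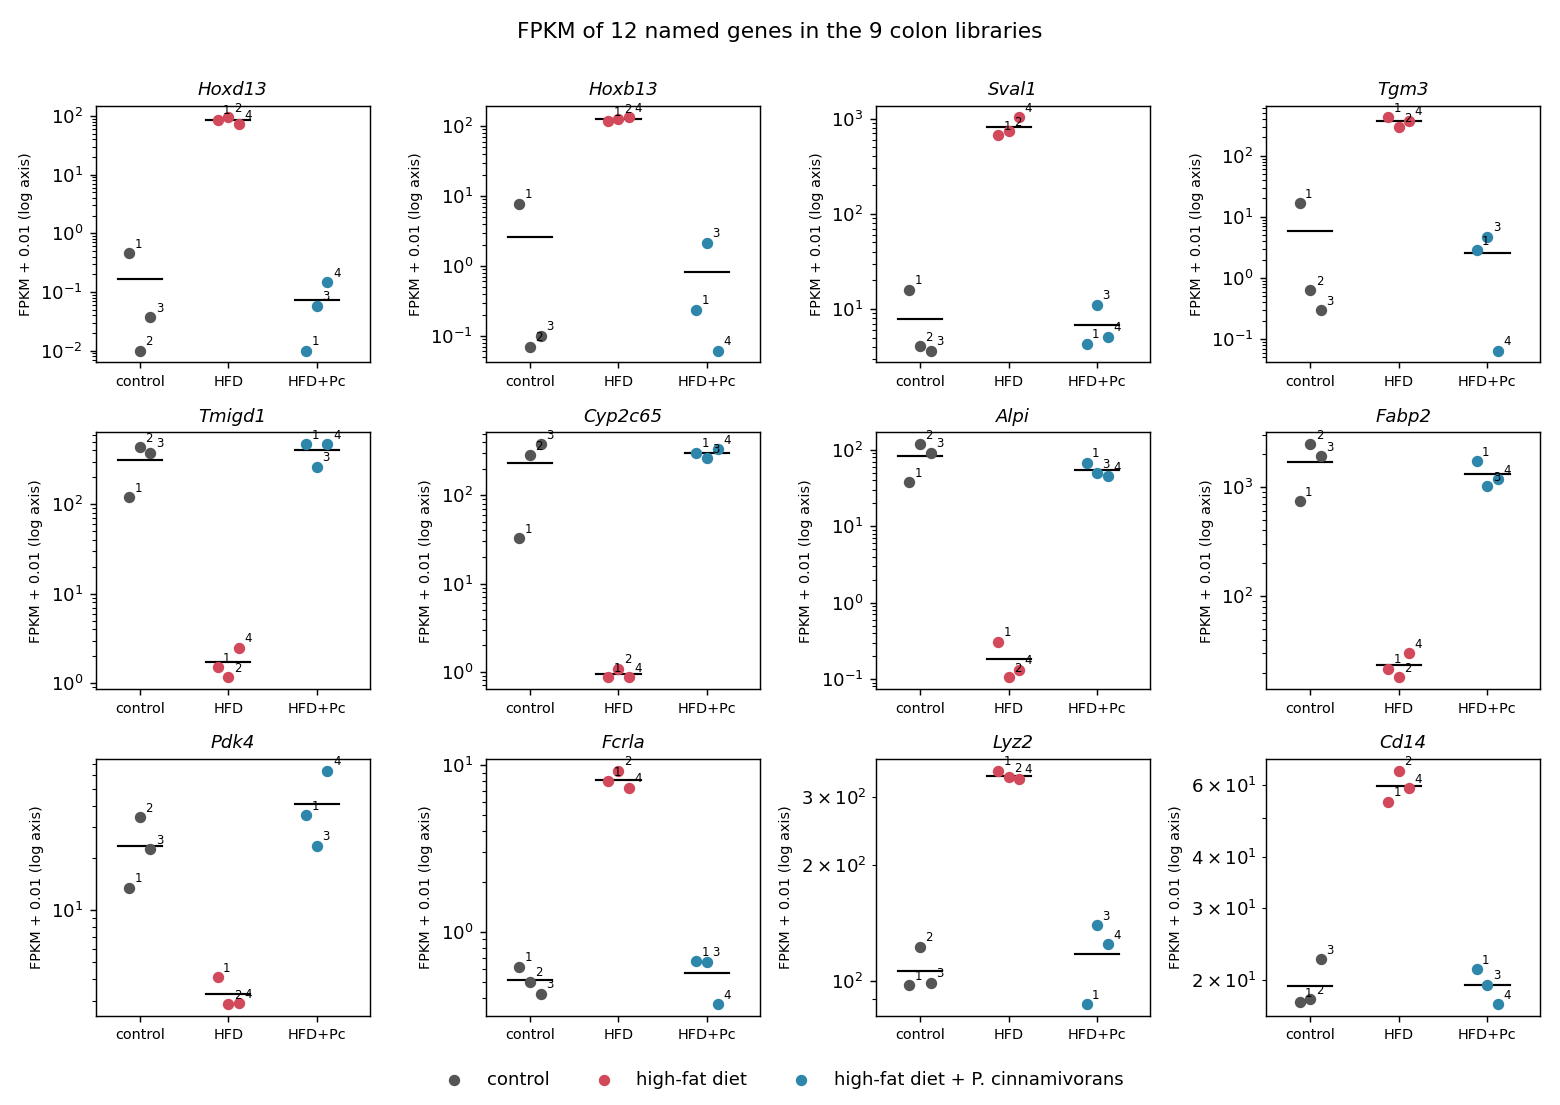
FPKM + 0.01 on a log axis of 12 named genes in each of the 9 libraries; each point is a library with its replicate number, and the line is the group mean. Hoxd13 lies between 72.6 and 94.3 FPKM in the 3 HFD libraries and at or below 0.45 FPKM in the other 6.

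Both comparisons share the HFD libraries, so their fold changes are negatively related by construction. Of the 1903 genes higher in HFD than in control, 1071 were called lower with the bacterium, where independent lists would share 144.6, and of the 1632 genes lower in HFD, 605 were called higher, where independent lists would share 74.1. In 20 simulated data sets without effects no gene was called in opposite directions. The independent lists leave out the shared libraries and the simulated data leave out the effects, so the excess over either is not read as a shared effect. Over all tested genes, 73.4% had opposite signs in these comparisons, against 66.7% in simulated data without effects. The covariance of the log2 differences across genes was -0.425, against -0.0419 on average in 20 simulated data sets without effects (-0.0452 to -0.0390), a difference of -0.384. The correlation across genes, which are not independent replicates, was -0.846 against -0.501 simulated. Part of this relation comes from the shared libraries. Noise in the simulated data was independent between genes. Deviations of a library shared by many genes were left out, so the simulated range is likely too narrow. The number of genes called in opposite directions, 1676 in all, was 798, 809 and 873 without HFD replicate 1, 2 or 4, and 1109 without replicate 1 of the group with the bacterium. The covariance was -0.244 without a filter and -0.915 with a pseudocount of 0.1.

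**Figure D3:**
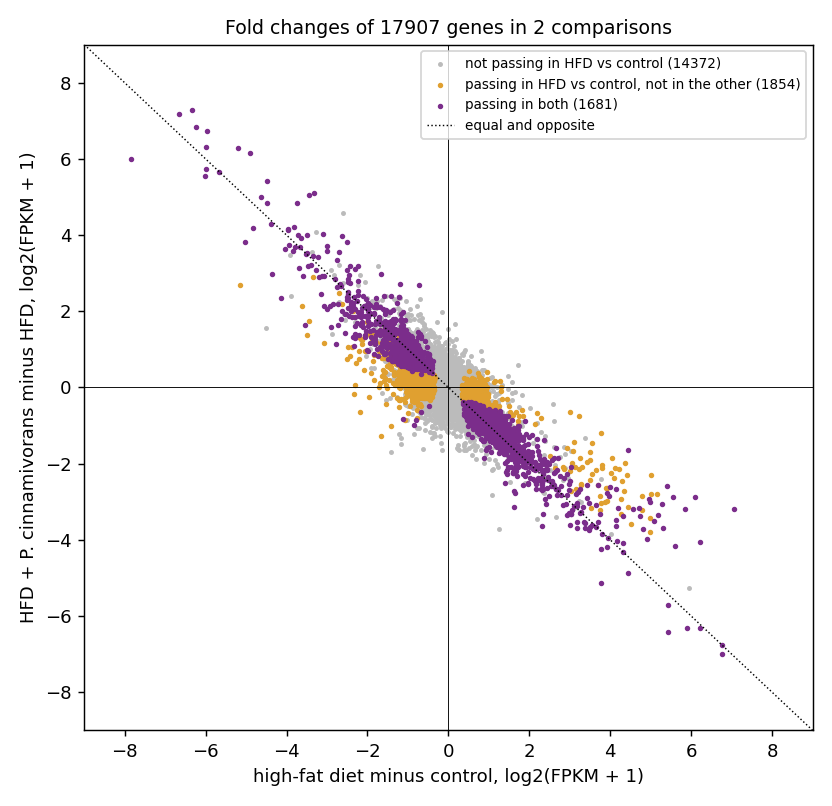
Difference of mean log2(FPKM + 1) of each of the 17907 tested genes in HFD against control (horizontal axis) and in HFD with the bacterium against HFD (vertical axis); colours mark genes passing in the first comparison and in both, and the dotted line marks equal and opposite values. The covariance was -0.425, against -0.0419 on average in simulated data without effects and with noise independent between genes.

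The comparison of HFD with P. cinnamivorans against control asks what remained different from control in mice given the diet and the bacterium. Few genes were called: 47 were higher and 151 lower. Atp5k, a subunit of ATP synthase, fell from 150 ± 17.2 to 19.4 ± 7.19 FPKM (log2 difference -2.95, SE 0.43, limma adjusted p = 0.037), Tmsb10 from 261 ± 32.5 to 55.9 ± 13.3 FPKM, and Rpl28 from 329 ± 11.3 to 110 ± 18.3 FPKM, and Klf4, a transcription factor of differentiated epithelium, fell by 1.23 on the log2 scale (SE 0.20). Tph1, the enzyme of serotonin synthesis in the gut, rose from 1.04 ± 0.148 to 2.87 ± 0.608 FPKM, Gimap4 from 6.92 ± 1.81 to 14.7 ± 2.04 FPKM and the mitochondrial transfer RNA mt-Ts2 from 22.8 ± 4.54 to 91.8 ± 19.4 FPKM. Atp5k, Tmsb10 and ribosomal protein genes have near-identical copies, so their values are uncertain. Of 84 ribosomal protein genes 9 fell and 0 rose, with a median log2 difference of -0.40, which was -0.10 after quantile normalization.

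Of 36 lists 11 passed camera, but none passed with an estimated correlation (adjusted p = 0.98 for each of the 11), and they held 1 called gene in all. The T and NK cell list had a median log2 difference of 0.29 with 0 of 25 genes called (0 adjusted over the list alone); Nkg7, a granule protein of cytotoxic lymphocytes, was at 13.2 ± 1.54 against 7.52 ± 2.77 FPKM (limma adjusted p = 0.11). The small intestine enterocyte list had a median of -0.61, the colonocyte list -0.30 and the hypoxia and glycolysis list -0.35, with 0 genes called in each (0, 0 and 3 lower adjusted over the list alone). Immediate early genes had a median of -0.37 with 1 of 20 called lower (4 adjusted over the list alone). The B and plasma cell list had a median of 0.44 with 0 of 23 genes called (0 adjusted over the list alone) and no longer passed after removal of mitochondrial and immunoglobulin genes. Of the other lists that passed, cell cycle had a median of 0.17, fatty acid and triglyceride synthesis -0.31, junction -0.27, oxidative phosphorylation -0.24 and cholesterol biosynthesis -0.23, with 0 genes called in each (0, 0, 0, 1 lower and 2 lower adjusted over the list alone). Krt20 was at 492 ± 121 against 903 ± 157 FPKM (limma adjusted p = 0.085) and Pkm at 100.2 ± 8.77 against 185 ± 23.7 FPKM (limma adjusted p = 0.053). Without control replicate 1 both were called lower, and Pkm was also called lower with a filter of 1 FPKM and after removal of mitochondrial and immunoglobulin genes. With fry 0 lists passed. The colonocyte, hypoxia and glycolysis, cholesterol, junction and oxidative phosphorylation lists no longer passed camera after quantile normalization, and immediate early genes and the cell cycle list did not without control replicate 1. The number of lists passing was 20 without control replicate 1 and 5 without control replicate 2. The number of called genes, 198, was 1187 without control replicate 1, 0 without control replicate 2 or 3, without HFD replicate 1 or without replicate 1 or 4 of the group with the bacterium, 3 without HFD replicate 2 and 115 without HFD replicate 4. Of the 13 named genes called here, 0 stayed called in every fit that left out 1 library. Across all tested genes, 3590 genes had an unadjusted p below 0.05. Only 2 genes were called by a fit of those 6 libraries alone. Mitochondrial transcripts took 28.2% ± 6.60 of summed FPKM with the bacterium and 21.7% ± 4.50 in control.

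Of the 20 genes fixed in advance for barrier, inflammation, lipid metabolism and hormones, 18 could be tested. In HFD against control 2 rose and 5 fell, with the bacterium against HFD 4 rose and 1 fell, and with the bacterium against control 0 passed. Tlr4 rose from 2.75 ± 0.205 FPKM in control to 5.73 ± 0.707 FPKM in HFD (limma adjusted p = 0.0049). It stayed at 5.04 ± 0.932 FPKM with the bacterium and was not called against HFD (limma adjusted p = 0.51). Without control replicate 1, Cpt1a, Fasn and Scd1 were also called lower in HFD than in control, Reg3g was called higher with the bacterium than in HFD, and against control Reg3g and Reg3b were called lower and Gcg higher with the bacterium. Pyy, a gut hormone, was at 67.7 ± 39.6, 165 ± 28.2 and 52.5 ± 7.36 FPKM in control, HFD and HFD with the bacterium. Pyy was not called in HFD against control without control replicate 2 or 3 or any HFD library, nor with the bacterium against HFD without HFD replicate 1 or 2 or replicate 4 of the group with the bacterium. Reg3b measured 128, 109 and 53.8 FPKM with the bacterium and was called against HFD, but not without HFD replicate 2 or 4 or replicate 1 of the group with the bacterium. The junction genes Tjp1 and Ocln passed in no comparison, with Tjp1 at 16.4 ± 2.18, 17.8 ± 0.334 and 15.9 ± 1.82 FPKM. Tnf was at 2.07 ± 0.932, 2.46 ± 0.948 and 1.11 ± 0.525 FPKM and did not pass in any comparison.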

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

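TPM scaling, removal of mitochondrial and immunoglobulin genes and the gene length adjustment were chosen after seeing the data. No called gene changed sign under any of the settings run. For HFD against control, genes higher and lower were 1125 and 860 with the replicate block and 3291 and 916 with TPM scaling. For the bacterium against HFD they were 478 and 810 with the replicate block, and 1484 were higher in a fit of only those groups. For the bacterium against control, higher and lower counts were 14 and 32 with quantile normalization, 4 and 11 without a filter, 71 and 231 with a filter of 1 FPKM, 0 and 2 with only those groups, 0 and 0 with the replicate block and 3 and 8 with TPM scaling; 74 were higher without mitochondrial and immunoglobulin genes and 99 lower with the length adjustment. Lists passing camera there were 6 with quantile normalization. With an estimated correlation 0 lists passed in any comparison, and fry passed 8, 7 and 0. Genes called opposite were 1019 with the replicate block, and the covariance was -0.244 without a filter and -0.915 with a pseudocount of 0.1. The cause of these changes was not tested.

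Leaving out 1 library at a time, genes higher and lower ranged from 909 to 2144 and from 703 to 2383 for HFD against control, from 380 to 1658 and from 611 to 1945 for the bacterium against HFD, and from 0 to 321 and from 0 to 866 for the bacterium against control. Lists passing camera ranged from 16 to 20, from 15 to 18 and from 5 to 20, genes called opposite from 798 to 2421 and the covariance from -0.455 to -0.404. Of the named genes called, 56 of 61, 49 of 58 and 0 of 13 stayed called in all 9 of these fits. Same-numbered libraries come from separate groups of mice, so the numbers do not pair mice, and the labels give no basis for the replicate block. Deviations of same-numbered libraries correlated between -0.16 and 0.19. Differently numbered libraries were not set beside them and no batch is given, so a batch shared by number stays open. Total depth is unknown, so no limit of detection is given. Tests that need counts were not run.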

Other observations

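The tests on Hox genes, genes of sodium and potassium handling, epithelial and other cell types, the variation between mice on the same diet and the diet response were chosen after the results had been seen, as was the length adjustment; the tests on scaling, gene length, control replicate 1 and other groupings were written before. Genes given here were chosen after their values were seen.

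The HFD libraries differed from the other 6 in genes that are known to mark position along the gut. Atp12a, the colonic proton and potassium pump, was at 84.5 ± 6.04 FPKM in HFD, 1.48 ± 2.13 in control and 0.696 ± 0.549 with the bacterium (SD, n = 3). Hoxb6 was at 1.14 ± 0.20 FPKM in HFD, 38.7 ± 29.7 in control and 33.9 ± 9.61 with the bacterium. Osr2 was at 0.156 ± 0.102, 23.9 ± 20.8 and 18.4 ± 1.57 FPKM in the same order, with 0.0162 FPKM in control replicate 1, and did not pass in either HFD comparison (limma adjusted p = 0.082 against control and 0.055 with the bacterium).

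Control replicate 1 lay apart from control replicates 2 and 3 in several genes. In control replicates 1, 2 and 3, Insl5 measured 73.6, 1.09 and 1.19 FPKM (104 to 120 in HFD), Mptx1 441, 2.64 and 1.82 FPKM (811 to 1450 in HFD) and Car1 603, 13000 and 19200 FPKM (56.0 to 118 in HFD), nearer to HFD in control replicate 1 in these 3 picked genes. Across all genes the measures differed. The correlation of control replicate 1 with HFD replicates 1, 2 and 4 was 0.872, 0.886 and 0.875. These values were lower than 0.889, 0.892 and 0.887 for control replicate 2 and 0.887, 0.894 and 0.890 for control replicate 3. On the first principal component control replicate 1 lay slightly nearer to HFD, at -30.6 against -39.3 and -39.6 for control replicates 2 and 3. Its deviation along the HFD axis had a correlation of 0.10 across genes, against -0.08 and -0.06 for control replicates 2 and 3. Of smooth muscle genes, control replicate 1 had the highest Des, Cnn1 and Myh11 of the 9 libraries: Des was at 1180, 242 and 160 FPKM, Cnn1 at 1050, 197 and 132 FPKM and Myh11 at 656, 189 and 134 FPKM in control replicates 1, 2 and 3. Whether that library came from the same stretch of colon as the other controls is not known, and the control means of such genes carry this doubt.

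A hypothesis is that the HFD pieces came from a more distal stretch of the colon than the others, which may account for part of the difference between HFD and both other groups. Posterior Hox genes had a median log2 difference of 1.95 between HFD and the other 6 libraries while Hoxb2 to Hoxb8 had -2.50 (-3.85 to -0.41). The list was made because Hoxd13 and Hoxb13 led the comparison. Its other posterior genes ranged from -0.85 (Hoxa11) to 2.67 (Hoxd12). Hoxd12 and Evx2 were at 0 FPKM in the other 6 libraries, and at 4.62 to 6.36 and 2.78 to 3.02 FPKM in HFD. Hoxd12, Hoxd13 and Evx2 passed the filter only through the HFD libraries, so the posterior median partly follows from the filter. For this reason, and since the list was made after the values were seen, it cannot decide. Of 4 genes of sodium and potassium handling in the distal colon (3 of channels and pumps, and Hsd11b2, an enzyme that inactivates glucocorticoids), also picked after the pattern was known and 3 of them from a list whose counts had been seen, the median was 1.26, as a distal stretch would give, but Scnn1b and Hsd11b2 did not pass and a hormonal effect of diet on these genes stays open. Different shares of mitochondrial and immunoglobulin transcripts are argued against, since 97.1% of the 3411 genes called in HFD against control and still measured were called in the same direction after their removal and rescaling, and deviations of single libraries of the control group or the group with the bacterium along the same axis reached a correlation across genes of 0.21 at the highest of 6, which leaves variation between mice on the same diet open. A diet response undone by the gavage has the covariance it needs (-0.425) and cannot be told apart from tissue position, because either would separate the same 3 libraries from the other 6.

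The higher immune lists in HFD may reflect more immune cells or fewer epithelial cells. The median of 7 pan-epithelial genes was -0.34, which met neither bound first set for a loss of epithelium; a second test was then set after that result. In it, enteric neuron and glia genes were lower (median -0.72, 9 of 25 called lower and 0 higher) while B cell genes were higher. With an estimated correlation in camera the adjusted p of the neuron list was 0.74. The medians of the fibroblast, endothelium and smooth muscle lists were 0.40, 0.07 and -0.64. The other cell types thus did not all rise alike. Because the list values were known when the second test was set, its outcome is not counted as support. Fewer epithelial cells alone would raise the other cell types alike. The B and plasma cell median was 2.58, against 0.40 for fibroblasts, 0.07 for endothelium and -0.72 for enteric neurons and glia. These medians argue against a lower epithelial share as the only cause of the B and plasma cell rise. A contribution of a lower epithelial share stays open. A larger number of immune cells, by diet or by position, stays open as well.

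Genes called with the bacterium against control had a median exonic length of 1960 bases, against 3541 for all tested genes, and 84 ribosomal protein genes had a median log2 difference of -0.40, while the 1450 shortest genes had a median of 0.00. A gene length bias could contribute: the correlation of the log2 difference with exonic length across genes was 0.124 (Spearman), between the bounds set beforehand. After the trend with gene length was removed, the ribosomal protein median was -0.31 and 5 of the 84 were called lower, against 9 as tested, and a contribution of gene length stays open. The median of ribosomal protein genes was -0.39 without control replicate 1, which argues against that library as the cause.

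Regrouping the 6 libraries of each comparison gives 10 splits, too few for a share under 0.05. The real split called 3535 genes in HFD against control and the highest other 1; it called 2174 with the bacterium against HFD and the highest other 1; and it called 198 with the bacterium against control and the highest other 0. In each comparison 1 of the 10 splits, the real one, gave as many. Every other split mixes libraries of both groups on each side. Any difference between the groups then adds to the spread, so few calls there follow by design. The contrast in calls is therefore not read as support for the real groups.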
